A study of Mus musculus with 27 samples.

How the data were processed

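Mixed glia were grown from the cortex of C57BL/6 mice a few days old, kept 14 days in vitro and treated for 24 h, per the labels' protocols. Doses per the labels were 50 nM bryostatin-1, 100 ng/mL LPS, 20 ng/mL IFN-gamma and 20 ng/mL IL-4. RNA libraries were unstranded and made from polyadenylated RNA, per the labels' protocols. The 27 libraries form 9 groups of 3, in 2 experiments that each have their own untreated group, and the groups were taken from the labels. The labels do not say whether replicates are separate cultures or animals, so p-values here measure the spread between these libraries, which may be technical. Reads were trimmed with fastp, aligned with STAR and counted with featureCounts on mm10, per the submitters' processing notes, with versions not given in the sources used here.

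The authors deposited raw read counts per gene (unit: counts, whole numbers with no normalization) for 54532 genes with their annotation, and the tests rest on these. The deposited FPKM values (unit: fpkm) equal the counts over the deposited gene length and the library total, times 1 constant per library (on the usual FPKM scale) of 0.901 to 1.19. The product of that constant with the TMM factor lies between 0.9824 and 1.01, so the authors' FPKM carry a scaling close to TMM. FPKM values were not used in tests. Names, biotypes, lengths and positions are those in the deposited annotation, where 103 symbols are repeated, and 2 genes of the fixed lists are not in it under their symbol. Total counts ran from 17230058 to 28687281, so 3 counts equal 0.105 to 0.174 CPM in a single library. Counting intervals (95%) and lower bounds cover counting error only. Where a group had 0 counts in all its libraries, the fold is a lower bound computed with 3 counts over the group, and with 1 to 3 counts the ratio has a counting interval.

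Counts were tested in R 4.3.3 with edgeR 4.0.16 (filterByExpr by group, TMM factors, quasi-likelihood fit with robust dispersion, quasi-likelihood F test), read with the package data.table (version 1.17.8). Experiments were fitted apart, each with all its groups and no other term, and p-values were adjusted by the Benjamini-Hochberg method over all genes of a comparison. A gene was called at an adjusted p under 0.05, and counts over 2-fold use the estimated fold of called genes. Values are log2 fold changes with their SE, and levels are mean CPM (counts per 1e6 counts of a library, scaled with TMM factors) ± SD, with n = 3 libraries per group throughout. Comparisons numbered 8 of group pairs, 2 of differences of bryostatin's effects and 1 of the untreated groups in a fit of all 27 libraries. Overlaps between comparisons were set against the product of the call rates. In 12 simulated data sets without a bryostatin effect too few bryostatin genes were called, at most 3 with LPS, to bound these overlaps, so they are not used.

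The comparisons, the tests, the alternatives and the 40 gene lists of immune responses, cell types, metabolism and signalling were chosen before the data were examined. Lists with at least 5 measured genes were tested with camera in limma 3.58.1 at a preset correlation of 0.01 between genes, 304 tests adjusted together, and again with an estimated correlation. Beside each list stand the genes called over all genes tested and the number called when adjusted over the list alone. The report describes the lists with the clearest shifts and those on inflammation, chosen after the list results were seen. Lists kept their call with an estimated correlation in 3 of 21 cases for bryostatin alone, 2 of 18 for IL-4, 6 of 18 for bryostatin with IL-4 and 15 of 23 for LPS. The numbers were 8 of 24 for bryostatin with LPS, 16 of 24 for LPS and IFN-gamma, 5 of 16 for bryostatin with both, and 6 of 22 for LPS and IFN-gamma against LPS.

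Genes were named by a rule fixed in advance. It takes the 8 largest and the 8 smallest fold changes among called protein-coding genes with a mean of at least 5 CPM in the higher group, a symbol that is not a clone name and, for group pairs, replicates that do not overlap. It also takes up to 4 called members of each described list, a fixed set of 19 glial and inflammatory genes, the 8 with the largest mean change each way among genes called alike in all 4 bryostatin comparisons, and 6 per direction of genes that bryostatin moved against the stimulus. Some genes that meet the rule are left out for length, and 2 others are not reported here. Genes outside it are marked as chosen after their values were seen. Without overlap between 3 and 3 libraries is what chance gives for 10% of genes.

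Alternatives were DESeq2 size factors in edgeR, DESeq2 1.42.0, no filter on low counts, only the compared groups in the fit, all 27 libraries in 1 fit, a replicate block, and leaving out each library in turn. A further pair, without both untreated libraries labelled replicate 1, and without these and replicate 2 of bryostatin and of IL-4 with bryostatin, was chosen after seeing the data. The fit was tested on simulated data with 200 genes changed. Averages are over 20 random draws, added after 2 single draws were seen. The fit recovered on average 44.6% of changes of 1.5-fold, 70.6% at 2-fold and 87.3% at 4-fold with LPS and bryostatin libraries. Unchanged genes made up 5.19% of calls on average (2.31% to 7.84%), over 5% in 12 draws. With bryostatin and untreated libraries of experiment 2 it recovered 11.5%, 56.6% and 85.2%, with 5.58% unchanged (2.8% to 11.3%), over 5% in 8 draws. Deviations shared by genes were not simulated, so these shares do not bound real errors. Figures used Python 3.11.15 and matplotlib 3.10.9.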

Results

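Gene expression was measured by RNA sequencing in 27 libraries of mixed glia from 2 experiments. Such cultures of newborn mouse cortex can hold astrocytes, microglia and oligodendrocyte-lineage cells. Experiment 1 had 15 libraries, 3 each of untreated glia, glia given lipopolysaccharide (LPS, a bacterial cell wall product that drives inflammation), LPS with bryostatin, LPS with interferon gamma (IFN-gamma), and LPS and IFN-gamma with bryostatin. Experiment 2 had 12 libraries, 3 each of untreated glia, glia given bryostatin, glia given interleukin 4 (IL-4, a cytokine of tissue repair and allergy), and IL-4 with bryostatin. Bryostatin-1 is a macrocyclic lactone that binds the C1 domain of protein kinase C. Total counts were highest in IL-4 with bryostatin replicate 1. Of 54532 annotated genes, 16073 had counts high enough to test in experiment 1 and 15604 in experiment 2.

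Oligodendrocyte precursor transcripts split the untreated libraries across the labels of the experiments. Sox10, a transcription factor of the oligodendrocyte lineage that was chosen after its values were seen, stood at 0.165 CPM in the library labelled untreated experiment 1 replicate 1, against 35.1 and 31.5 CPM in replicates 2 and 3. It stood at 36.5 CPM in the library labelled untreated experiment 2 replicate 1, against 0.273 and 0.222 CPM in the other replicates of that group. Pdgfra, the growth factor receptor of precursors, divided the same libraries, at 4.03 CPM against 141 and 161 CPM in experiment 1 and at 89.9 CPM against 5.24 and 5.27 CPM in experiment 2. Across genes, the library labelled untreated experiment 1 replicate 1 had a Pearson r of 0.993 with both other libraries of the other experiment's untreated group, and of 0.955 and 0.956 with its own. The library labelled untreated experiment 2 replicate 1 had an r of 0.978 and 0.967 with the other experiment's and of 0.945 and 0.934 with its own. Labels were kept as given, and each comparison with untreated glia has its count without both libraries. Untreated glia of the experiments, compared as labelled in edgeR, gave 0 called genes of 16647 tested, with 1573 at an unadjusted p under 0.05 against 832 expected, and DESeq2 also called 0. Without both libraries labelled replicate 1, 3165 genes differed.

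**Figure D1:**
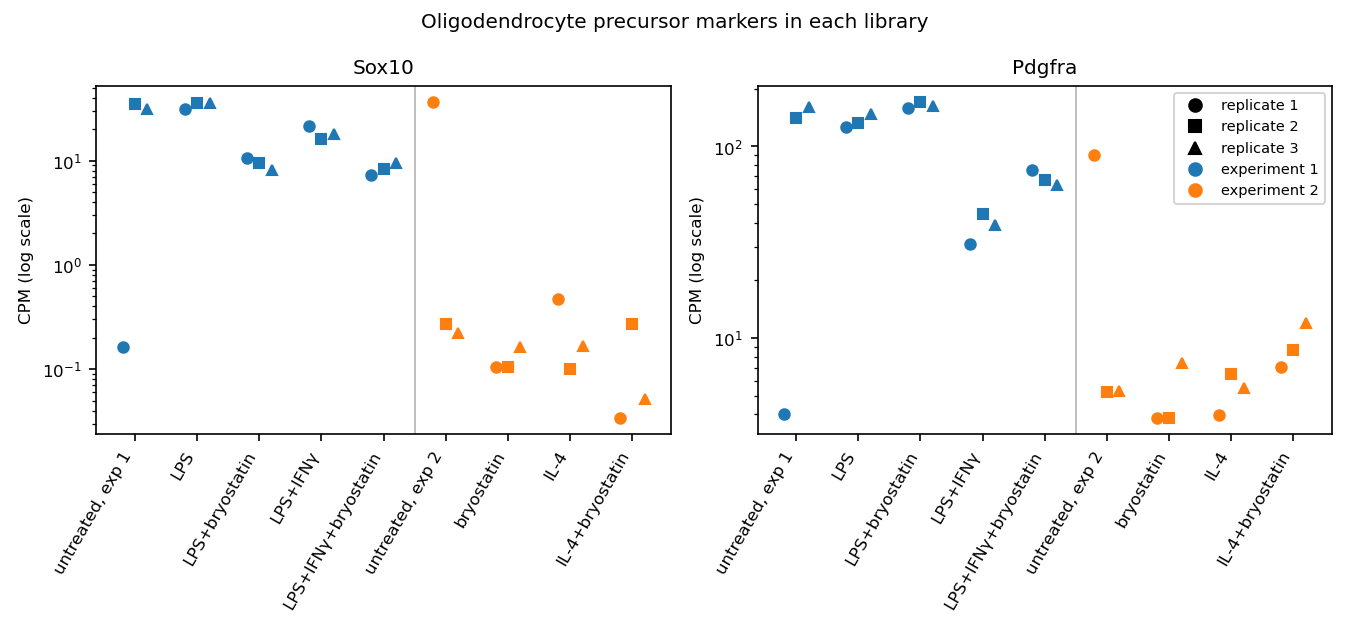
Sox10 and Pdgfra in CPM (log axis) in each of the 27 libraries by group, blue for experiment 1 and orange for experiment 2, with circles, squares and triangles for replicates 1, 2 and 3. Sox10 lies at 0.165 CPM in the circle of untreated experiment 1 and at 36.5 CPM in that of untreated experiment 2, each among the values of the other experiment.

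LPS, given to ask how glia respond to a bacterial signal, raised inflammatory and antiviral genes by large factors. The chemokine gene Ccl5 rose by a log2 fold change of 9.88 ± 0.27 (adjusted p = 2e-13), from 2.03 ± 0.995 CPM to 1910 ± 142 CPM. Nos2, which makes nitric oxide, rose by 9.84 ± 0.29 (adjusted p = 1.7e-13), and Lcn2, an iron-binding acute phase protein, by 8.43 ± 0.18 (adjusted p = 1.1e-14), to 7310 ± 213 CPM. The cytokine genes Il6 (8.21 ± 0.3), Il1b (7.15 ± 0.36) and Tnf (3.85 ± 0.19) rose, as did complement C3 (3.29 ± 0.15) and the itaconate enzyme Acod1 (7.79 ± 0.16). Il12b, with 1 count in untreated glia, had a ratio of 95.6 (95% counting interval 16.7 to 3820), and Il10 a ratio of 38 (10.2 to 320). The receptor Gpr34 of resting microglia fell with a log2 change of -6.62 ± 0.51 (adjusted p = 3e-08), and so did the transporter Slco2b1 (-6.11 ± 0.34) and the protease Capn3 (-5.8 ± 0.59). Trem2, a microglial lipid receptor, fell with a log2 change of -3.33 ± 0.18 (adjusted p = 3.6e-10), and Mrc1 (-2.88 ± 0.27), Igf1 (-1.63 ± 0.16) and the astrocyte filament Gfap (-0.88 ± 0.1) fell too. In total 6164 genes of 16073 were called, 3141 higher and 3023 lower, of which 1295 rose and 958 fell over 2-fold. Without both untreated libraries labelled replicate 1, 7032 were called.

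All interferon-stimulated genes measured rose with LPS, such as Mx1 (7.27 ± 0.17) and Oas3 (6.3 ± 0.17): 34 rose, 0 fell and 0 were not called of 34 measured. Interferon-stimulated genes numbered 34 up and 0 down adjusted over the list alone (camera adjusted p = 7.6e-100, or 0.00203 with an estimated correlation). For class I antigen presentation (H2-K1, 4.35 ± 0.11), 20 rose, 0 fell and 0 were not called of 20 measured. Class I genes numbered 20 up and 0 down adjusted over the list alone (camera adjusted p = 1.15e-96, or 0.000689 with an estimated correlation). Among guanylate-binding proteins and targets of IFN-gamma, 30 rose, 1 fell and 1 was not called of 32 measured. IFN-gamma targets numbered 30 up and 1 down adjusted over the list alone (camera adjusted p = 4.22e-75, or 0.00173 with an estimated correlation). Chemokine genes followed, as 24 rose, 0 fell and 1 was not called of 25 measured, and of cytokines and enzymes of inflammation, 18 rose, 0 fell and 0 were not called of 18 measured. Chemokine genes numbered 24 up and 0 down adjusted over the list alone (camera adjusted p = 3.22e-75, or 0.000689 with an estimated correlation). Inflammatory cytokine genes numbered 18 up and 0 down adjusted over the list alone (camera adjusted p = 3.83e-35, or 0.000806 with an estimated correlation). Homeostatic microglial genes went the other way, as 1 rose, 18 fell and 1 was not called of 20 measured, among them Cx3cr1 (-1.76 ± 0.11) and Fcrls (-2.86 ± 0.17). Homeostatic genes numbered 1 up and 18 down adjusted over the list alone (camera adjusted p = 8.66e-12, or 0.000689 with an estimated correlation). Cell cycle genes such as Rrm2 (-1.12 ± 0.12) and Top2a (-0.93 ± 0.12) fell: 0 rose, 30 fell and 6 were not called of 36 measured. Cell cycle genes numbered 0 up and 31 down adjusted over the list alone (camera adjusted p = 9.94e-08, or 0.199 with an estimated correlation). In the astrocyte identity list, which includes Slc39a12 (-3.11 ± 0.08), 2 rose, 16 fell and 8 were not called of 26 measured. Astrocyte identity genes numbered 2 up and 17 down adjusted over the list alone (camera adjusted p = 1.04e-05, or 0.263 with an estimated correlation).

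LPS with IFN-gamma, against untreated glia, raised targets of IFN-gamma and genes of class II antigen presentation. The chemokine gene Cxcl9 rose by 15.07 ± 0.34 (adjusted p = 8.9e-15), to 3180 ± 271 CPM, and Nos2 by 13.27 ± 0.28 (adjusted p = 2.6e-15), to 914 ± 82.1 CPM. Serpina3f, a protease inhibitor with near copies beside it, had 0 counts in untreated glia and was at least 1440-fold higher. Ciita, the switch of class II genes, rose by 7.11 ± 0.21, and Cd74, the class II invariant chain, by 7.78 ± 0.17. Il12b, from 1 count in untreated glia, had a ratio of 2280 (counting interval 409 to 90300). Mrc1 fell with a log2 change of -6.28 ± 0.37 (adjusted p = 5.8e-10), the glutamine synthetase gene Glul with -2.61 ± 0.08 and the myelin gene Mbp with -0.98 ± 0.24 (adjusted p = 0.0025). Il10 was not called, at a ratio of 2.49 (counting interval 0.358 to 27.6, adjusted p = 0.48). In all, 9339 genes were called, 4743 higher and 4596 lower, of which 1919 rose and 2151 fell over 2-fold, and 9997 were called without both untreated libraries labelled replicate 1. Every measured guanylate-binding and IFN-gamma target rose: 32 rose, 0 fell and 0 were not called of 32 measured. IFN-gamma targets numbered 32 up and 0 down adjusted over the list alone (camera adjusted p = 1.22e-92, or 0.000689 with an estimated correlation). Of the class II genes, 12 rose, 0 fell and 3 were not called of 15 measured. Class II genes numbered 12 up and 1 down adjusted over the list alone (camera adjusted p = 1.99e-20, or 0.00591 with an estimated correlation). Most astrocyte identity genes fell, as 1 rose, 21 fell and 4 were not called of 26 measured. Astrocyte identity genes numbered 2 up and 22 down adjusted over the list alone (camera adjusted p = 4.69e-10, or 0.123 with an estimated correlation).

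Set against LPS alone, LPS with IFN-gamma asks what the interferon adds. Class II genes such as H2-Eb1 (5.59 ± 0.17, adjusted p = 2e-12) and Cd74 (4.26 ± 0.14, adjusted p = 4.8e-12) rose, Cd74 from 38.1 ± 2.9 to 726 ± 126 CPM. Ramp3, a receptor accessory protein, rose by 7.28 ± 0.34 (adjusted p = 2e-10), the migration receptor Ccr7 by 6.06 ± 0.35, Nos2 by 3.43 ± 0.15, the co-stimulatory receptor Cd86 by 3.18 ± 0.19 and Il6 by 0.91 ± 0.15 (adjusted p = 0.00018). Il10 fell with a log2 change of -3.81 ± 0.8 (adjusted p = 0.0014), Mrc1 with -3.39 ± 0.4, Arg1 with -1.15 ± 0.2 (adjusted p = 0.00034) and Spp1 with -1.66 ± 0.12. Il1b (0.16 ± 0.25, adjusted p = 0.65), Tnf (0.29 ± 0.15, adjusted p = 0.14) and Lcn2 (0.1 ± 0.13, adjusted p = 0.56) were not called. The call counts were 3094 higher and 2697 lower, 5791 in all, with 829 up and 976 down over 2-fold and 4631 to 5239 genes on leaving out each of the 6 libraries in turn. In the NRF2 and oxidative stress list, with the glutathione genes Gclm (2.71 ± 0.08) and Slc7a11 (2.53 ± 0.17), 20 rose, 0 fell and 3 were not called of 23 measured. NRF2 targets numbered 22 up and 0 down adjusted over the list alone (camera adjusted p = 7.47e-21, or 0.0164 with an estimated correlation). In the sterol synthesis list (Lss, 1.36 ± 0.08), 24 rose, 0 fell and 2 were not called of 26 measured. Sterol synthesis genes numbered 24 up and 0 down adjusted over the list alone (camera adjusted p = 1.61e-12, or 0.0521 with an estimated correlation). For ATF4 and unfolded protein targets (Trib3, 2.91 ± 0.2), 18 rose, 3 fell and 2 were not called of 23 measured. ATF4 targets numbered 18 up and 3 down adjusted over the list alone (camera adjusted p = 6.61e-12, or 0.0598 with an estimated correlation). Class II presentation genes rose, as 13 rose, 0 fell and 2 were not called of 15 measured. Class II genes numbered 13 up and 0 down adjusted over the list alone (camera adjusted p = 3.88e-46, or 0.000689 with an estimated correlation).

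IL-4, given to ask how glia enter a repair-like state, raised a small and steep set of genes. Arg1, the arginase of alternatively activated macrophages, rose by 10.58 ± 0.38 (adjusted p = 1.3e-07), from 0.34 ± 0.303 CPM to 555 ± 78 CPM. The secreted protein genes Retnla and Chil3 had 0 counts in untreated glia and were at least 1500-fold and 354-fold higher, reaching 81 ± 29.6 and 19.3 ± 11.3 CPM. The lectin Mgl2, with 1 count in untreated glia, had a ratio of 1040 (counting interval 186 to 41100). Ccl24 (6.35 ± 0.5, adjusted p = 8.9e-05), Itgax (5.13 ± 0.41), Pecam1 (5.02 ± 0.36) and the growth factor Igf1 (1.45 ± 0.21, adjusted p = 0.0069) rose, and Mrc1 rose by 1.93 ± 0.26 (adjusted p = 0.0031). Gpr34 (-1.94 ± 0.2, adjusted p = 0.00041), Cx3cr1 (-1.16 ± 0.13, adjusted p = 0.00091), the fungal lectin Clec4n (-2.63 ± 0.32) and the LPS co-receptor Cd14 (-1.74 ± 0.22) fell. Not called were Tnf (-1.33 ± 0.36, adjusted p = 0.23), Il1b (-0.87 ± 0.41, adjusted p = 0.45), C3 (-0.09 ± 0.25, adjusted p = 0.86), Lcn2 (-0.93 ± 0.41, adjusted p = 0.45) and Gfap (-0.37 ± 0.16, adjusted p = 0.45). Of 15604 genes, 91 were called, 78 higher and 13 lower, and 70 of those that rose did so over 2-fold. Without both untreated libraries labelled replicate 1, 89 genes were called and 8 of 18 list calls were lost, none of them for a list described here. Of the named genes with IL-4, Lmo2 lost its call, from -0.82 ± 0.16 (adjusted p = 0.045) to -0.82 (adjusted p = 0.0884), as did Ccna2 and Mmp10, and Anpep gained one. For the alternative activation list, 12 rose, 0 fell and 17 were not called of 29 measured. Alternative activation genes numbered 24 up and 1 down adjusted over the list alone (camera adjusted p = 1.01e-91, or 0.000689 with an estimated correlation). Homeostatic microglial genes fell in part, as 0 rose, 3 fell and 18 were not called of 21 measured. Homeostatic genes numbered 0 up and 6 down adjusted over the list alone (camera adjusted p = 5.41e-06, or 0.0898 with an estimated correlation). Pecam1 and Flt1 (2.59 ± 0.21, also in the alternative activation list) rose in the endothelial list (median -0.09, mean 0.56). There 2 rose, 0 fell and 10 were not called of 12 measured. Endothelial genes numbered 2 up and 0 down adjusted over the list alone (camera adjusted p = 2.43e-05, or 0.0398 with an estimated correlation). Chemokines split, with a median of -0.13 and a mean of 0.74, and 5 rose, 0 fell and 12 were not called of 17 measured. Chemokine genes numbered 5 up and 2 down adjusted over the list alone (camera adjusted p = 1.23e-05, or 0.247 with an estimated correlation). Of class II genes, 2 rose, 0 fell and 12 were not called of 14 measured. Class II genes numbered 2 up and 0 down adjusted over the list alone (camera adjusted p = 0.00269, or 0.394 with an estimated correlation).

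Bryostatin alone, against untreated glia of experiment 2, raised part of the chemokine and matrix protease lists. Arg1 rose by 4.44 ± 0.37 (adjusted p = 0.00022), from 0.34 ± 0.303 to 7.82 ± 1.72 CPM. The monocyte chemokines Ccl2 (3.77 ± 0.28, adjusted p = 0.00015), Ccl12 (2.84 ± 0.16, adjusted p = 2.3e-05) and Ccl6 (3.39 ± 0.31) rose, and the matrix phosphoprotein gene Spp1 rose by 2.57 ± 0.18 (adjusted p = 0.00012), to 2170 ± 229 CPM from 366 ± 63.6 CPM. Mmp3, a matrix protease, rose by 2.57 ± 0.22, the urokinase receptor Plaur by 1.81 ± 0.21, the lipid oxidase Alox15 by 3.28 ± 0.43 and the innate receptor Trem1 by 3.11 ± 0.4. Mmp10 had 0 counts in untreated glia and was at least 17.1-fold higher. Gja1, the astrocyte gap junction protein, fell with a log2 change of -1.13 ± 0.16 (adjusted p = 0.0034), and the sodium pump subunit Atp1b2 with -0.69 ± 0.1, the sterol enzyme Hmgcs1 with -0.84 ± 0.09 (adjusted p = 0.0011) and complement C1s1 with -0.91 ± 0.11. The water channel Aqp4 fell with a log2 change of -0.95 ± 0.18 (adjusted p = 0.018), and its adjusted p was 0.0602 without bryostatin replicate 1. The fixed genes Mrc1, C3 and Gfap were called and lost the call without both untreated libraries labelled replicate 1, with Mrc1 at 1.28 ± 0.25 (adjusted p = 0.021) and then 1.16 (adjusted p = 0.0587), C3 at -1.19 ± 0.25 (adjusted p = 0.029) and then -0.97 (adjusted p = 0.0587), and Gfap at -0.67 ± 0.16 (adjusted p = 0.042) and then -0.52 (adjusted p = 0.0616). Of the 6 fits that each left out 1 library, Mrc1 was called without bryostatin replicate 2 and untreated experiment 2 replicate 3, C3 without untreated experiment 2 replicate 2 and untreated experiment 2 replicate 3 and Gfap without bryostatin replicate 2 and untreated experiment 2 replicate 3. Across all alternatives the adjusted p of Mrc1 ran over 9.2e-05 to 0.18, that of C3 over 3e-04 to 0.17, that of Gfap over 0.00088 to 0.34 and that of Aqp4 over 1.9e-05 to 0.25. Il1b (-0.71 ± 0.41, adjusted p = 0.38), Tnf (0.07 ± 0.34, adjusted p = 0.94), Cd86 (0.61 ± 0.25, adjusted p = 0.22), Trem2 (0.14 ± 0.24, adjusted p = 0.8), Igf1 (0.26 ± 0.21, adjusted p = 0.56), Lcn2 (1.26 ± 0.41, adjusted p = 0.12) and Pdgfra (-2.78 ± 0.94, adjusted p = 0.13) were not called.

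Of 15604 genes, 565 were called with bryostatin alone, 329 higher and 236 lower, and 144 rose and 94 fell over 2-fold. The count was 429 without both untreated libraries labelled replicate 1, of which 358 were among the 565. In that fit 7 of 21 list calls were lost, of the lists described here that of interferon-stimulated genes (adjusted p = 0.63), and 20 named genes lost the call while Tubb3 gained it and so did Lcn2, at 1.73 (adjusted p = 0.0427). Genes higher made up 58.2% of the calls, but 77.7% without bryostatin replicate 1, and 40.5% and 42.2% without untreated experiment 2 replicates 2 and 3, which turns the majority. The nuclear RNA Malat1, chosen after its values were seen, stood at 92.6 CPM in bryostatin replicate 2 and 74.9 CPM in untreated experiment 2 replicate 1, against 161 to 653 CPM in the other 4 libraries. The count was 188 without bryostatin replicate 1, 265 without bryostatin replicate 3, and 9 when only these 6 libraries entered the fit. Cell cycle genes such as Ccna2 (0.79 ± 0.09) and Bub1b (0.71 ± 0.11) rose by small amounts: 17 rose, 0 fell and 19 were not called of 36 measured. Cell cycle genes numbered 33 up and 0 down adjusted over the list alone (camera adjusted p = 8.53e-29, or 0.00748 with an estimated correlation). Chemokine genes rose in part, as 7 rose, 1 fell and 9 were not called of 17 measured. Chemokine genes numbered 8 up and 1 down adjusted over the list alone (camera adjusted p = 5.87e-16, or 0.0424 with an estimated correlation). For matrix proteases and the plasminogen system, 7 rose, 1 fell and 16 were not called of 24 measured. Matrix genes numbered 10 up and 2 down adjusted over the list alone (camera adjusted p = 2.13e-10, or 0.0381 with an estimated correlation). In the alternative activation list, 7 rose, 0 fell and 22 were not called of 29 measured. Alternative activation genes numbered 8 up and 0 down adjusted over the list alone (camera adjusted p = 1.33e-09, or 0.0738 with an estimated correlation). Disease-associated microglial genes such as Gpnmb (1.53 ± 0.2) moved with the microglia and macrophage core (Itgam, 1.27 ± 0.14); of the former 5 rose, 0 fell and 23 were not called of 28 measured, and of the latter 5 rose, 0 fell and 20 were not called of 25 measured. Disease-associated genes numbered 6 up and 0 down adjusted over the list alone (camera adjusted p = 4.97e-08, or 0.0956 with an estimated correlation). Microglial core genes numbered 6 up and 0 down adjusted over the list alone (camera adjusted p = 8.97e-07, or 0.396 with an estimated correlation). In the astrocyte identity list, 1 rose, 10 fell and 14 were not called of 25 measured. Astrocyte identity genes numbered 1 up and 19 down adjusted over the list alone (camera adjusted p = 1.13e-14, or 0.0791 with an estimated correlation). Sterol synthesis genes fell in part, as 0 rose, 4 fell and 22 were not called of 26 measured. Sterol synthesis genes numbered 0 up and 5 down adjusted over the list alone (camera adjusted p = 3.12e-07, or 0.146 with an estimated correlation). Ependymal genes, of motile cilia, had a median of -1.64, or -0.73 without both untreated libraries labelled replicate 1, and 0 rose, 0 fell and 11 were not called of 11 measured. Ependymal genes numbered 0 up and 11 down adjusted over the list alone (camera adjusted p = 6.03e-07, or 0.289 with an estimated correlation). No single interferon-stimulated gene or inflammatory cytokine was called, with medians of -0.21 and 0.03: of the first, 0 rose, 0 fell and 33 were not called of 33 measured, and of the second, 0 rose, 0 fell and 11 were not called of 11 measured. Interferon-stimulated genes numbered 0 up and 0 down adjusted over the list alone (camera adjusted p = 0.0246, or 0.62 with an estimated correlation). Inflammatory cytokine genes numbered 0 up and 0 down adjusted over the list alone (camera adjusted p = 0.817, or 0.917 with an estimated correlation).

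Bryostatin given with IL-4, against IL-4 alone, raised several of the genes that IL-4 itself raised. Arg1 rose a further 1.83 ± 0.23 (adjusted p = 0.0024), from 555 ± 78 CPM to 1960 ± 172 CPM, and Mgl2 by 2.69 ± 0.21 (adjusted p = 1e-04). Ccl12 rose by 3.75 ± 0.16 (adjusted p = 1.1e-06), Ccl2 by 3.28 ± 0.26, Spp1 by 2.7 ± 0.18 (adjusted p = 7.6e-05), the macrophage elastase Mmp12 by 2.06 ± 0.22, urokinase Plau by 2.06 ± 0.15 and the IL-4 receptor Il4ra by 0.87 ± 0.13 (adjusted p = 0.0043). Mrc1 rose by 1.45 ± 0.25 (adjusted p = 0.0095), and its adjusted p rose past the threshold without IL-4 with bryostatin replicate 3 (0.054) and IL-4 replicate 1 (0.0506). Hmgcs1 fell with a log2 change of -1.02 ± 0.09 (adjusted p = 0.00023), from 350 ± 16.7 to 171 ± 3.68 CPM, the matrix protein Myoc with -2.74 ± 0.42 and Slc39a12, a zinc transporter of astrocytes, with -0.84 ± 0.13. Retnla (-0.9 ± 0.32, adjusted p = 0.18), Chil3 (0.73 ± 0.42, adjusted p = 0.45), Igf1 (0.12 ± 0.21, adjusted p = 0.86), Trem2 (0.59 ± 0.24, adjusted p = 0.24), Tnf (0.16 ± 0.37, adjusted p = 0.9), Il1b (-0.81 ± 0.44, adjusted p = 0.41) and Gfap (-0.43 ± 0.16, adjusted p = 0.18) were not called. C3 fell with a log2 change of -1.15 ± 0.25 (adjusted p = 0.029), Lcn2 rose by 1.71 ± 0.42 (adjusted p = 0.045) and Cd74 fell with a log2 change of -1.29 ± 0.24 (adjusted p = 0.014), but across all alternatives their adjusted p ran over 0.00037 to 0.13, 6e-04 to 0.17 and 1.8e-05 to 0.075. Of the 6 fits that each left out 1 library, C3 was called without IL-4 replicate 1, Cd74 without IL-4 replicate 1 and Lcn2 in none.

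In all, 644 genes were called with IL-4, 422 higher and 222 lower, of which 159 rose and 61 fell over 2-fold. Leaving out a library lowered the count to 277, 196 and 172 without IL-4 with bryostatin replicates 1, 2 and 3, and to 193, 191 and 371 without IL-4 replicates 1, 2 and 3. The count was 1355 without both untreated libraries labelled replicate 1, which are not in this comparison. Cell cycle genes rose with bryostatin here too (Cdk1, 0.7 ± 0.1), as 22 rose, 0 fell and 14 were not called of 36 measured. Cell cycle genes numbered 34 up and 0 down adjusted over the list alone (camera adjusted p = 4.21e-31, or 0.00577 with an estimated correlation). Of the chemokines, 8 rose, 1 fell and 8 were not called of 17 measured. Chemokine genes numbered 9 up and 2 down adjusted over the list alone (camera adjusted p = 2.85e-21, or 0.0239 with an estimated correlation). Sterol synthesis genes such as Hmgcs1 fell, as 0 rose, 8 fell and 18 were not called of 26 measured. Sterol synthesis genes numbered 0 up and 14 down adjusted over the list alone (camera adjusted p = 1.32e-15, or 0.037 with an estimated correlation). In the alternative activation list, 10 rose, 0 fell and 19 were not called of 29 measured. Alternative activation genes numbered 13 up and 2 down adjusted over the list alone (camera adjusted p = 4.11e-13, or 0.0381 with an estimated correlation). Disease-associated microglial genes such as Gpnmb (1.46 ± 0.2) rose: 10 rose, 0 fell and 18 were not called of 28 measured. Disease-associated genes numbered 13 up and 1 down adjusted over the list alone (camera adjusted p = 3.58e-12, or 0.0398 with an estimated correlation). For matrix proteases and the plasminogen system, 9 rose, 1 fell and 14 were not called of 24 measured. Matrix genes numbered 10 up and 1 down adjusted over the list alone (camera adjusted p = 1.18e-11, or 0.0286 with an estimated correlation). In the microglia and macrophage core, 6 rose, 1 fell and 18 were not called of 25 measured, and in the astrocyte identity list, 1 rose, 8 fell and 16 were not called of 25 measured. Microglial core genes numbered 13 up and 1 down adjusted over the list alone (camera adjusted p = 5.03e-13, or 0.196 with an estimated correlation). Astrocyte identity genes numbered 1 up and 12 down adjusted over the list alone (camera adjusted p = 6.69e-10, or 0.152 with an estimated correlation).

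Bryostatin given with LPS, against LPS alone, lowered antigen presentation and complement genes without a call in most cytokine genes. The class II genes H2-Aa (-3.08 ± 0.34, adjusted p = 5.3e-05) and Cd74 (-1.82 ± 0.14, adjusted p = 1.8e-06) fell, Cd74 from 38.1 ± 2.9 to 10.7 ± 1.16 CPM. The chemokines Cxcl13 (-3.11 ± 0.27, adjusted p = 4e-06), Ccl22 (-3 ± 0.23, adjusted p = 1.8e-06) and Cxcl9 (-1.45 ± 0.17) fell. Chil1, a chitinase-like protein of reactive astrocytes, fell with a log2 change of -2.2 ± 0.1 (adjusted p = 1e-08), from 1380 ± 61.9 to 298 ± 11.5 CPM. Complement genes fell as well, C1s1 with -1.27 ± 0.07 (adjusted p = 4.7e-08) and C3 with -1 ± 0.14 (adjusted p = 0.00032), and Lcn2 fell with a log2 change of -0.69 ± 0.13 (adjusted p = 0.0028), from 7310 ± 213 to 4480 ± 166 CPM. The endothelial and tumour-associated proteoglycan gene Esm1 rose by 3.55 ± 0.22 (adjusted p = 1.1e-07), Spp1 by 2 ± 0.12 (adjusted p = 8.3e-08) and the neuropeptide Npy by 2.58 ± 0.27. Il1b (-0.16 ± 0.25, adjusted p = 0.8), Il6 (0.22 ± 0.15, adjusted p = 0.46), Nos2 (-0.39 ± 0.14, adjusted p = 0.11), Il12b (-1.09 ± 0.43, adjusted p = 0.17), Mrc1 (0.33 ± 0.27, adjusted p = 0.58), Trem2 (0.02 ± 0.19, adjusted p = 0.97), Igf1 (0.06 ± 0.17, adjusted p = 0.91) and Gfap (-0.19 ± 0.1, adjusted p = 0.35) were not called. Tnf fell with a log2 change of -0.6 ± 0.15 (adjusted p = 0.025), Arg1 rose by 0.76 ± 0.19 (adjusted p = 0.023) and Cd86 rose by 0.76 ± 0.19 (adjusted p = 0.026), and across all alternatives their adjusted p ran over 9.1e-05 to 0.13, 6.8e-07 to 0.11 and 7.6e-05 to 0.13. Of the 6 fits that each left out 1 library, Tnf was called without LPS with bryostatin replicate 3, Arg1 without LPS with bryostatin replicate 3 and Cd86 without LPS replicate 3 and LPS with bryostatin replicate 1.

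With LPS, 1108 of 16073 genes were called for bryostatin, 538 higher and 570 lower, of which 133 rose and 149 fell over 2-fold. The count became 588, 620 and 618 without LPS replicates 1, 2 and 3, and 654, 595 and 689 without LPS with bryostatin replicates 1, 2 and 3. The count was 2148 without both untreated libraries labelled replicate 1, which are not in this comparison. Class I presentation genes such as H2-Q7 (-1.1 ± 0.11) and H2-D1 (-0.51 ± 0.1) fell: 0 rose, 13 fell and 7 were not called of 20 measured. Class I genes numbered 0 up and 16 down adjusted over the list alone (camera adjusted p = 1.23e-16, or 0.0424 with an estimated correlation). For class II, 1 rose, 6 fell and 8 were not called of 15 measured. Class II genes numbered 1 up and 8 down adjusted over the list alone (camera adjusted p = 7.47e-11, or 0.0286 with an estimated correlation). Guanylate-binding proteins and IFN-gamma targets (Gbp10, -1.35 ± 0.22) fell in part, as 0 rose, 11 fell and 21 were not called of 32 measured. IFN-gamma targets numbered 1 up and 17 down adjusted over the list alone (camera adjusted p = 1.2e-11, or 0.164 with an estimated correlation). Feedback genes of NF-kB such as Nfkbie (-0.79 ± 0.11) fell, as 0 rose, 5 fell and 17 were not called of 22 measured. NF-kB feedback genes numbered 0 up and 16 down adjusted over the list alone (camera adjusted p = 2.7e-11, or 0.0367 with an estimated correlation). In the complement list, 0 rose, 7 fell and 12 were not called of 19 measured. Complement genes numbered 0 up and 9 down adjusted over the list alone (camera adjusted p = 1.58e-10, or 0.00173 with an estimated correlation). Of the microglia and macrophage core, 1 rose, 12 fell and 12 were not called of 25 measured, and of astrocyte identity genes such as Slc1a3 (-0.87 ± 0.08), 1 rose, 8 fell and 17 were not called of 26 measured. Microglial core genes numbered 1 up and 14 down adjusted over the list alone (camera adjusted p = 5.69e-11, or 0.0899 with an estimated correlation). Astrocyte identity genes numbered 1 up and 13 down adjusted over the list alone (camera adjusted p = 6.09e-11, or 0.0948 with an estimated correlation). Matrix genes rose, with Mmp11 at 1.5 ± 0.12: 11 rose, 2 fell and 13 were not called of 26 measured. Matrix genes numbered 14 up and 3 down adjusted over the list alone (camera adjusted p = 6.37e-09, or 0.029 with an estimated correlation). In the list of astrocyte genes known as A2, with Tm4sf1 (1.01 ± 0.13), 4 rose, 0 fell and 8 were not called of 12 measured. A2 genes numbered 4 up and 0 down adjusted over the list alone (camera adjusted p = 2.55e-05, or 0.00783 with an estimated correlation). For trophic and pro-myelinating factors, 10 rose, 4 fell and 19 were not called of 33 measured. Trophic factors numbered 11 up and 5 down adjusted over the list alone (camera adjusted p = 8.04e-05, or 0.0398 with an estimated correlation). Neuronal markers such as Nefl (1.99 ± 0.33) moved with them, and 4 rose, 0 fell and 13 were not called of 17 measured. Neuronal markers numbered 5 up and 0 down adjusted over the list alone (camera adjusted p = 2.31e-06, or 0.113 with an estimated correlation). Inflammatory cytokines did not move as a set, as 1 rose, 2 fell and 15 were not called of 18 measured, and of interferon-stimulated genes 0 rose, 1 fell and 33 were not called of 34 measured. Inflammatory cytokine genes numbered 1 up and 2 down adjusted over the list alone (camera adjusted p = 0.806, or 0.925 with an estimated correlation). Interferon-stimulated genes numbered 0 up and 1 down adjusted over the list alone (camera adjusted p = 0.0123, or 0.723 with an estimated correlation).

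Where glia had LPS and IFN-gamma, bryostatin again raised Esm1 (2.63 ± 0.22, adjusted p = 8.9e-06), Spp1 (1.57 ± 0.12, adjusted p = 3.6e-06) and Arg1 (1.17 ± 0.2, adjusted p = 0.0041). The opioid precursor gene Penk rose by 2.14 ± 0.18 (adjusted p = 1.3e-05), from 32.5 ± 2.44 to 143 ± 25.2 CPM, the synaptic pentraxin Nptx1 by 1.84 ± 0.16 (adjusted p = 2e-05) and the endothelial receptor Cd93 by 2.65 ± 0.28. The inducible heat shock genes Hspa1a (-1.98 ± 0.15, adjusted p = 3.6e-06) and Hspa1b (-1.5 ± 0.11), which are near-identical copies, fell, Hspa1a from 36.9 ± 4.65 to 9.31 ± 0.941 CPM. The prostaglandin-degrading enzyme Hpgd (-2.37 ± 0.29), Myoc (-2.1 ± 0.3), Aqp4 (-1.28 ± 0.13), the acute phase gene Serpina3n (-1.32 ± 0.15) and class II H2-Eb1 (-1.01 ± 0.13, adjusted p = 0.00028) fell. Cd74 fell with a log2 change of -0.63 ± 0.12 (adjusted p = 0.009), C3 with -0.66 ± 0.14 (adjusted p = 0.015) and Gfap with -0.51 ± 0.1 (adjusted p = 0.011), and Il6 rose by 0.73 ± 0.15 (adjusted p = 0.011). Calls were lost, with the adjusted p in parentheses, for Cd74 without LPS and IFN-gamma with bryostatin replicate 1 (0.0505), for C3 without LPS and IFN-gamma with bryostatin replicate 1 (0.0681), LPS and IFN-gamma with bryostatin replicate 3 (0.0647) and LPS and IFN-gamma replicate 3 (0.0646), for Gfap without LPS and IFN-gamma with bryostatin replicate 1 (0.0501) and for Il6 without LPS and IFN-gamma with bryostatin replicate 3 (0.0526). Nos2 (0.48 ± 0.13, adjusted p = 0.064), Tnf (-0.37 ± 0.15, adjusted p = 0.23), Il1b (0.45 ± 0.25, adjusted p = 0.43), Il12b (-0.48 ± 0.25, adjusted p = 0.39), Lcn2 (-0.46 ± 0.13, adjusted p = 0.061), Cd86 (0.14 ± 0.17, adjusted p = 0.79), Mrc1 (0.36 ± 0.56, adjusted p = 0.85), Igf1 (-0.61 ± 0.19, adjusted p = 0.11) and Trem2 (0.07 ± 0.19, adjusted p = 0.93) were not called.

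The bryostatin calls with LPS and IFN-gamma numbered 543, 289 higher and 254 lower, with 82 up and 54 down over 2-fold. The 543 became 309, 251 and 337 without LPS and IFN-gamma with bryostatin replicates 1, 2 and 3, and 313 and 242 without LPS and IFN-gamma replicates 2 and 3. The count was 1380 without both untreated libraries labelled replicate 1, which are not in this comparison. Astrocyte identity genes fell, as 1 rose, 7 fell and 18 were not called of 26 measured. Astrocyte identity genes numbered 1 up and 12 down adjusted over the list alone (camera adjusted p = 3.73e-16, or 0.0424 with an estimated correlation). Matrix genes such as Mmp3 (0.83 ± 0.1) rose: 7 rose, 0 fell and 19 were not called of 26 measured. Matrix genes numbered 11 up and 1 down adjusted over the list alone (camera adjusted p = 3.72e-11, or 0.0164 with an estimated correlation). For class II presentation, 0 rose, 6 fell and 9 were not called of 15 measured, and for class I, 0 rose, 2 fell and 18 were not called of 20 measured. Class II genes numbered 0 up and 7 down adjusted over the list alone (camera adjusted p = 4.02e-09, or 0.0398 with an estimated correlation). Class I genes numbered 0 up and 7 down adjusted over the list alone (camera adjusted p = 1.06e-05, or 0.263 with an estimated correlation). In the complement list, 0 rose, 4 fell and 15 were not called of 19 measured. Complement genes numbered 0 up and 4 down adjusted over the list alone (camera adjusted p = 0.000136, or 0.0286 with an estimated correlation). Of trophic and pro-myelinating factors such as Tgfb1 (0.77 ± 0.1), 9 rose, 2 fell and 22 were not called of 33 measured. Trophic factors numbered 13 up and 6 down adjusted over the list alone (camera adjusted p = 0.000164, or 0.0424 with an estimated correlation). Neuronal markers moved with these, and 3 rose, 0 fell and 14 were not called of 17 measured. Neuronal markers numbered 6 up and 0 down adjusted over the list alone (camera adjusted p = 4.62e-05, or 0.17 with an estimated correlation). In the microglia and macrophage core, 0 rose, 5 fell and 20 were not called of 25 measured. Microglial core genes numbered 0 up and 7 down adjusted over the list alone (camera adjusted p = 1.47e-06, or 0.207 with an estimated correlation). Inflammatory cytokines were higher as a set, as 3 rose, 0 fell and 15 were not called of 18 measured, and of the guanylate-binding and IFN-gamma targets 1 rose, 0 fell and 31 were not called of 32 measured. Inflammatory cytokine genes numbered 4 up and 0 down adjusted over the list alone (camera adjusted p = 0.00753, or 0.304 with an estimated correlation). IFN-gamma targets numbered 1 up and 0 down adjusted over the list alone (camera adjusted p = 0.988, or 0.996 with an estimated correlation).

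**Figure D2:**
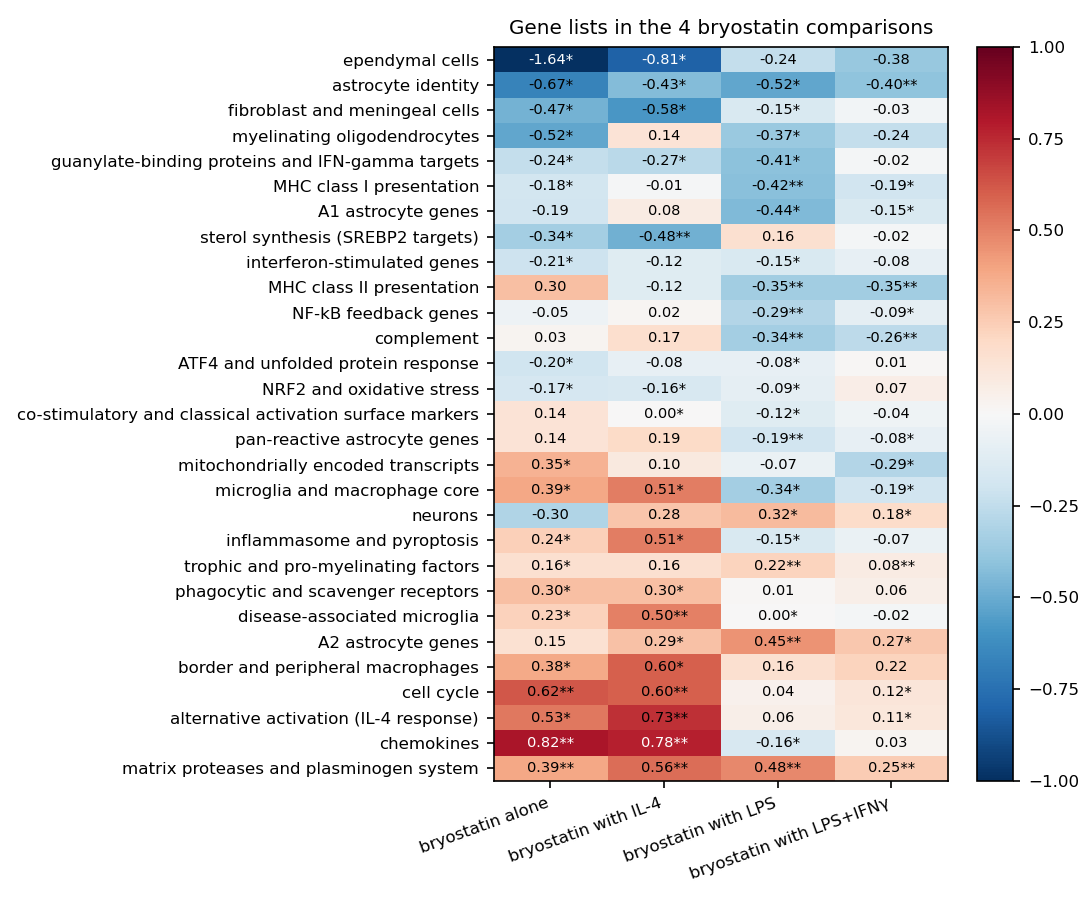
Median log2 fold change of gene lists (color, capped at 1 in either direction) in the 4 bryostatin comparisons, for lists called in at least 2 of them, with * for a camera adjusted p under 0.05 with a preset correlation and ** where the estimated correlation also gives it. Astrocyte identity lies at -0.67, -0.43, -0.52 and -0.4 and matrix proteases at 0.39, 0.56, 0.48 and 0.25, for bryostatin alone and with IL-4, LPS, and LPS and IFN-gamma.

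A test of the difference between bryostatin's effects asked whether IFN-gamma changes what bryostatin does in LPS-treated glia. Ccl22, a chemokine of dendritic cells, differed by 3.49 ± 0.28 (adjusted p = 2.5e-05), with -3 under LPS and 0.49 under LPS and IFN-gamma. C1s1, a complement protease, differed by 0.96 ± 0.1 (adjusted p = 0.00031), with -1.27 and -0.31. For Hspa1b the difference was -1.39 ± 0.16 (adjusted p = 0.00092), with -0.11 under LPS and -1.5 with IFN-gamma, and for its copy Hspa1a it was -1.57 ± 0.22 (adjusted p = 0.0081). The immediate early gene Egr1 went from 0.79 to -0.99, a difference of -1.78 ± 0.26 (adjusted p = 0.013). Of 16073 genes, 19 were called, 11 higher and 8 lower, with 1021 at an unadjusted p under 0.05 against 804 expected. The count became 4, 11 and 12 without LPS replicates 1, 2 and 3, 11 and 9 without LPS with bryostatin replicates 1 and 3, 10 without LPS and IFN-gamma replicate 2 or 3, and 6 and 9 without LPS and IFN-gamma with bryostatin replicates 2 and 3. Ccl22, C1s1, Hspa1a and Hspa1b were called in each of these fits, and Egr1 lost its call without LPS and IFN-gamma with bryostatin replicates 2 (adjusted p = 0.0672) and 3 (0.0559) and without LPS replicate 1 (0.0577). Bryostatin's effect with IL-4, less its effect alone, gave 0 called genes of 15604 in edgeR, with 327 at an unadjusted p under 0.05 against 780 expected and 2 called in DESeq2.

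**Figure D3:**
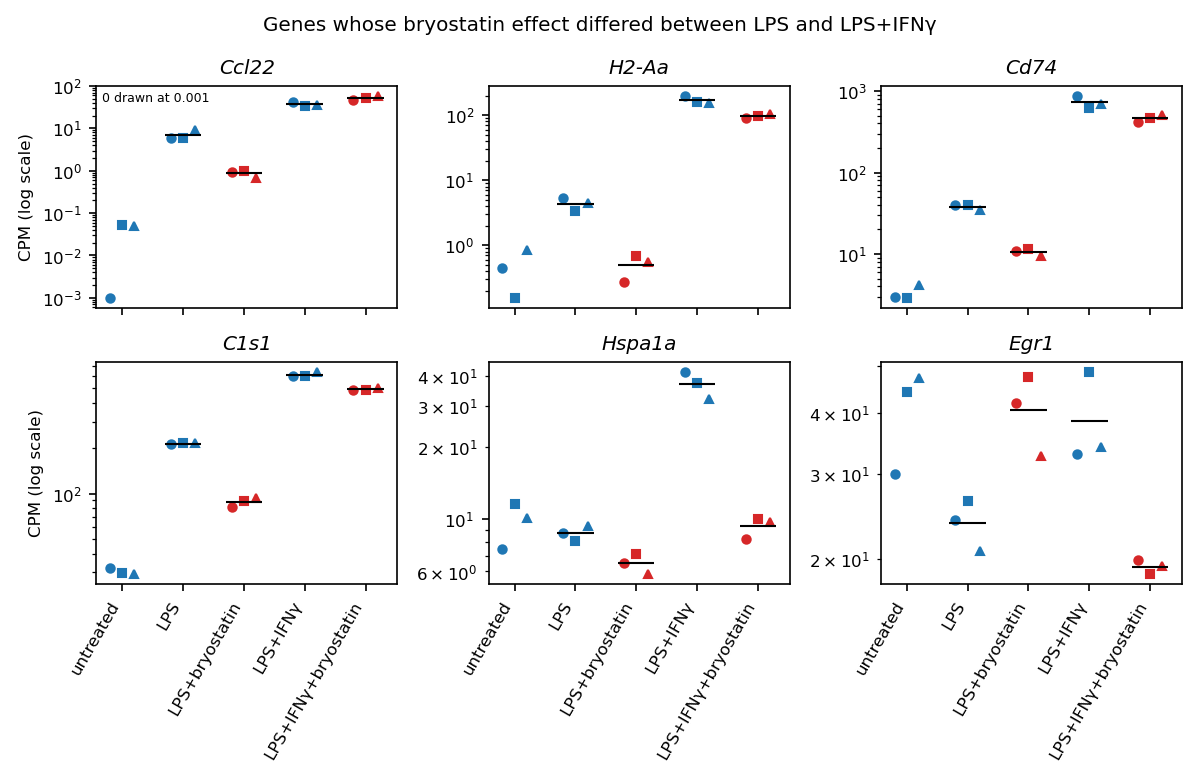
CPM (log axis, 0 drawn at 0.001) of Ccl22, H2-Aa, Cd74, C1s1, Hspa1a and Egr1 in each library of experiment 1, red with bryostatin and blue without, with a black line at the mean of treated groups. H2-Aa, Cd74 and Egr1 lost the call of the difference when some single libraries were left out, and Hspa1a lies at 9.31 ± 0.941 CPM (mean ± SD, n = 3) with bryostatin, LPS and IFN-gamma, against 36.9 ± 4.65 CPM without bryostatin.

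Across all 4 bryostatin comparisons, 26 genes were called higher each time and 31 lower each time, of 15243 tested in both experiments. Independent calls would give 0.005 and 0.0018. Spp1 rose by 2.57 alone, 2.7 with IL-4, 2 with LPS and 1.57 with LPS and IFN-gamma. For Esm1 these values were 1.74, 1.8, 3.55 and 2.63, for Npy 1.82, 1.79, 2.58 and 2.42, and for the retinoic acid enzyme Aldh1a3 2.26, 1.9, 1.78 and 2.02. Arg1 rose by 4.44, 1.83, 0.76 and 1.17. Among those that fell, Myoc had log2 changes of -2.69, -2.74, -2.78 and -2.1, the ion exchanger Slc24a4 of -1.75, -1.65, -1.7 and -1.75, and Aqp4 of -0.95, -1.1, -0.78 and -1.28. The 26 became 16 without bryostatin replicate 1, 14 and 15 without IL-4 replicates 1 and 2, and 16 without IL-4 with bryostatin replicate 2 or 3. The 31 became 9 and 20 without bryostatin replicates 1 and 3, 16 without IL-4 replicate 1 or 2, and 17, 13 and 17 without IL-4 with bryostatin replicates 1, 2 and 3. They became 19 without LPS and IFN-gamma replicate 3 and 20, 17 and 20 without LPS and IFN-gamma with bryostatin replicates 1, 2 and 3. Fits of only the groups compared gave 2 and 0. In at least 3 comparisons, 80 genes were higher and 75 lower. Bryostatin alone and with IL-4 shared 358 called genes, all in the same direction, with no library in common. Both come from 1 fit that shares its estimate of the spread, so their calls are not independent. The 358 became 163 and 221 without bryostatin replicates 1 and 3, 150 and 156 without IL-4 replicates 1 and 2, and 201, 160 and 147 without IL-4 with bryostatin replicates 1, 2 and 3, again all in the same direction. Fits of only the groups compared gave 9. Bryostatin with LPS and with LPS and IFN-gamma, again with none in common, shared 338, of which 336 moved the same way. Pairs across experiments shared 161, 91, 172 and 103, of which 15, 8, 13 and 8 went opposite ways. The 338 became 217 and 172 without LPS and IFN-gamma replicates 2 and 3, and 217 and 184 without LPS and IFN-gamma with bryostatin replicates 1 and 2.

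**Figure D4:**
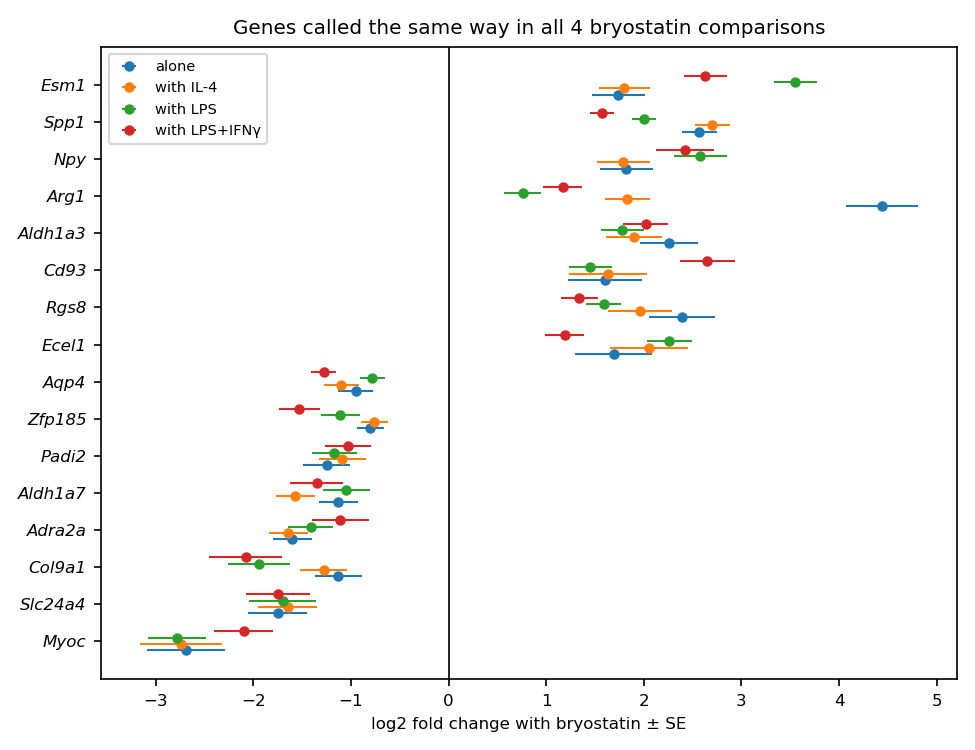
Log2 fold change ± SE (edgeR, n = 3 libraries per group) of 16 genes in the 4 bryostatin comparisons, the 8 with the largest mean rise and the 8 with the largest mean fall among genes called the same way each time. Arg1 spreads from 0.76 to 4.44 and Myoc from -2.78 to -2.1.

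Whether bryostatin opposes a stimulus was read from genes called for both. Of 3141 genes that LPS raised, bryostatin lowered 295, against 111 if the calls were independent, and raised 157, against 105. Among them Cxcl9 rose by 9.31 ± 0.35 with LPS and fell with a log2 change of -1.45 ± 0.17 (adjusted p = 1e-04) with bryostatin, and H2-Q6 had 8.87 ± 0.21 and -1.11 ± 0.13. Of 3023 genes that LPS lowered, 137 were higher with bryostatin (101 expected) and 146 lower (107 expected). For LPS and IFN-gamma, 109 of 4743 raised genes were lower with bryostatin (75 expected) and 126 higher (85.3 expected), and of 4596 lowered genes 75 were higher (82.6 expected) and 103 lower (72.6 expected). For IL-4, 35 of 78 raised genes were higher still with bryostatin (2.11 expected) and 3 lower (1.11 expected), and of 13 lowered genes 4 were higher (0.352 expected) and 2 lower (0.185 expected). Those 4 were the receptors Gpr34 (1.08 ± 0.19), P2ry13 (1.04 ± 0.18) and Clec4d (1.53 ± 0.26) and the regulator Lmo2 (1.49 ± 0.16), and they became 1, 0 and 2 without IL-4 replicate 1, IL-4 replicate 2 and IL-4 with bryostatin replicate 3. The 3 that IL-4 raised and bryostatin lowered became 6 and 1 without IL-4 replicates 1 and 2, and 0, 1 and 1 without IL-4 with bryostatin replicates 1, 2 and 3. The stimulus libraries enter both sides of each overlap with opposite sign, which by itself adds opposite calls, to an extent that was not measured. In place of the 295, leaving out a library gave 172, 178 and 181 without LPS replicates 1, 2 and 3 and 185, 187 and 186 without LPS with bryostatin replicates 1, 2 and 3. The lowest counts so reached were 82 (without LPS replicate 1) in place of 157, 64 (without LPS replicate 3) in place of 137 and 64 (without LPS replicate 1) in place of 146. In place of the 109 it gave 54 and 48 without LPS and IFN-gamma replicates 2 and 3, and 45, 39 and 68 without LPS and IFN-gamma with bryostatin replicates 1, 2 and 3. The lowest were 55 in place of 126 and 23 in place of 75 (both without LPS and IFN-gamma replicate 3), and 53 in place of 103 (without LPS and IFN-gamma replicate 2). In place of the 35 it gave 16, 14 and 23 without IL-4 replicates 1, 2 and 3, and 22, 17 and 14 without IL-4 with bryostatin replicates 1, 2 and 3.

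Oligodendrocyte markers carry the doubt they raise on the untreated libraries. Pdgfra was not called in any of the 8 comparisons as labelled, with 0.42 ± 0.67 (adjusted p = 0.66) for LPS, -1.4 ± 0.7 (adjusted p = 0.1) for LPS and IFN-gamma, -2.7 ± 0.93 (adjusted p = 0.43) for IL-4, -1.82 ± 0.71 (adjusted p = 0.06) for IFN-gamma added to LPS, 0.29 ± 0.67 (adjusted p = 0.88) for bryostatin with LPS, 0.86 ± 0.7 (adjusted p = 0.64) with LPS and IFN-gamma and 0.8 ± 0.92 (adjusted p = 0.76) with IL-4. Without both untreated libraries labelled replicate 1, Pdgfra was called for LPS and IFN-gamma at -1.96 (adjusted p = 6.28e-11), for IFN-gamma added to LPS at -1.82 (adjusted p = 2.22e-10) and for bryostatin with LPS and IFN-gamma at 0.86 (adjusted p = 5.46e-05), and Mbp for LPS at -0.69 (adjusted p = 0.000533), for IFN-gamma added to LPS at -0.59 (adjusted p = 0.00198) and for bryostatin with IL-4 at 0.64 (adjusted p = 0.0248). As labelled, Mbp stood at 0 ± 0.33 (adjusted p = 1) for bryostatin alone, 0.65 ± 0.33 (adjusted p = 0.38) with IL-4 and -0.11 ± 0.24 (adjusted p = 0.87) with LPS, and was not called there.

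Positions are on mm10 and gene identifiers are Ensembl's. Arg1 is ENSMUSG00000019987, chromosome 10, 24915221 to 24927484. Spp1 is ENSMUSG00000029304, chromosome 5, 104435118 to 104441050. Ccl2 is ENSMUSG00000035385, chromosome 11, 82035571 to 82037453. Esm1 is ENSMUSG00000042379, chromosome 13, 113209659 to 113218098. Cd74 is ENSMUSG00000024610, chromosome 18, 60803848 to 60812646. Hspa1a is ENSMUSG00000091971, chromosome 17, 34969190 to 34972156. Hspa1b is ENSMUSG00000090877, chromosome 17, 34956436 to 34959238. Near-identical or overlapping genes share reads in unstranded libraries, so values of Hspa1a and Hspa1b, H2-Q6 and H2-Q7, and single members of the guanylate-binding, Slfn and Serpina3 families carry an uncertainty that their errors do not show.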

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

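The difference of bryostatin's effects was a planned test, and the count of other splits of the libraries was chosen after the result was seen. Below, a positive value means that bryostatin's effect was higher under LPS and IFN-gamma than under LPS alone.

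By edgeR's test of the difference itself, 19 single genes differed between the 2 settings, and no gene list was tested on the difference. Of the 16 that the rule names, only Ccl22, C1s1, Hspa1a and Hspa1b kept the call when each library was left out in turn. Bryostatin's effect on Ccl22 was -3 under LPS, where it was called, and 0.49 with IFN-gamma, where it was not, a difference of 3.49 on the log2 scale. For the class II gene H2-Aa the difference was 2.28 (-3.08 under LPS, -0.8 with IFN-gamma), and for the invariant chain Cd74 it was 1.19 (-1.82 and -0.63). Ubd, a ubiquitin-like protein induced by interferon, differed by 1.96 (-1.42 and 0.54), the protease inhibitor Serpina3g by 1.56, the guanylate-binding protein Gbp11 by 1.48 (-2.01 and -0.53) and the ion channel Calhm6 by 1.28. The chitinase-like gene Chil1 differed by 0.99 (-2.2 and -1.21), the complement protease C1s1 by 0.96 (-1.27 and -0.31), the interleukin 18 inhibitor Il18bp by 0.89 and the matrix gene Podn by 0.85.

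Lower under LPS and IFN-gamma than under LPS were the early response gene Egr1 (-1.78), the heat shock genes Hspa1a (-1.57) and Hspa1b (-1.39), the DNA repair gene Fancc (-0.99), the receptor Il6ra (-0.98), the stress gene Gadd45a (-0.81), the lipase Mgll (-0.76) and the retinol enzyme Rdh10 (-0.62). Of these 19, Gbp11, Il18bp and Podn fall outside the rule for naming genes and were chosen after their values were seen. Regrouping libraries within the arms gave as many calls in 3 of 50 splits, the real one included. The other large ones, with 83 and 41, kept the groups of 1 arm and so its bryostatin effect, which leaves chance undecided. For IL-4 the real count was 0, as in all 50 splits, which decides nothing there. No explanation was tested for the 19 genes.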

How the results depend on the processing

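Tests without the untreated libraries labelled replicate 1, and without these and replicate 2 of bryostatin and of IL-4 with bryostatin (the bryostatin-2 libraries), were chosen after the results were seen, as were the other splits of the libraries. All other alternatives were planned.

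No alternative reversed a call of a named gene, and none of those run on lists reversed a list call. Of named gene values, 14101 had no recorded change of call (uncalled genes could change sign), 1149 lost a call and 191 gained one. Of list calls, 1153 were kept and 175 lost. Genes called in every alternative and with each library left out numbered 171 of 171 named for LPS and IFN-gamma, 169 of 173 for LPS and 155 of 163 for LPS and IFN-gamma against LPS. They were 26 of 41 for IL-4, 9 of 97 for bryostatin alone, 49 of 104 for bryostatin with IL-4, 92 of 130 with LPS and 46 of 97 with LPS and IFN-gamma. The counts for LPS, for LPS and IFN-gamma and for LPS and IFN-gamma against LPS stayed within 1.5 times the reported count in every alternative.

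The cause was not tested for the shifts in this paragraph. With DESeq2, 1266 genes were called in place of 565 for bryostatin alone, 214 in place of 91 for IL-4, 1117 in place of 644 for bryostatin with IL-4 and 850 in place of 543 for bryostatin with LPS and IFN-gamma. The difference with IL-4 gave 2 in place of 0 and that with LPS and IFN-gamma 89 in place of 19. Genes higher in all 4 bryostatin comparisons became 45 from 26 and those lower 55 from 31, genes raised by IL-4 and lower with bryostatin 5 from 3, and those raised by LPS and IFN-gamma and lower with bryostatin 171 from 109. With no filter on low counts the difference with LPS and IFN-gamma gave 55 and genes raised by IL-4 and lower with bryostatin 6. The share of called genes that were higher also moved for bryostatin alone, from 58.2% in edgeR to 48.1% in DESeq2. It was 40.5% to 77.7% with 1 library left out.

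Fits of only the groups compared have fewer libraries to estimate the spread. They called 9 genes for bryostatin alone, 41 for IL-4, 2703 for bryostatin with IL-4, 3354 for bryostatin with LPS and 112 for the difference with LPS and IFN-gamma, with 2 genes higher and 0 lower in all 4 bryostatin comparisons and 615 raised by LPS and lower with bryostatin. All 27 libraries in 1 fit gave 1548 for bryostatin alone, 224 for IL-4, 1325 for bryostatin with IL-4, 5 for the difference with IL-4 and 7 for that with LPS and IFN-gamma. The overlaps of raised and then lower genes were 9 for IL-4, 184 for LPS and 54 for LPS and IFN-gamma in that fit.

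Without the untreated libraries labelled replicate 1, counts rose to 1355 for bryostatin with IL-4, 2148 with LPS and 1380 with LPS and IFN-gamma, to 114 for the difference with LPS and IFN-gamma and to 3165 for the untreated groups. Genes higher in all 4 became 40 and lower 71, and raised and then lower genes 500 for LPS and 270 for LPS and IFN-gamma. All groups of an experiment share 1 estimate of the spread, so these libraries also enter comparisons that hold no untreated library. For bryostatin with LPS, Sox10 kept its log2 change of -1.85 while its SE went from 0.74 to 0.12. Cspg4 kept 0.89 with an SE of 0.14 and then 0.11. Calls there thus depend on a spread that these libraries widen for some genes. Other causes were not tested. Without the bryostatin-2 libraries as well, 2284 genes were called for bryostatin alone, 333 for IL-4, 2943 for bryostatin with IL-4 and 1 for the difference with IL-4, with 52 higher in all 4 and 19 raised by IL-4 and lower with bryostatin. These fits have bryostatin groups of 2 libraries.

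A replicate block gave 422 genes for bryostatin alone, 94 for IL-4, 564 for bryostatin with IL-4, 963 with LPS and 464 with LPS and IFN-gamma, and 0 and 19 for the differences. The labels give replicates only a number, and the data hint at pairing at most in part. In experiment 1, 9 of 15 libraries correlated best with those of their own number, where chance gives 1 in 3, but 3 of 30 same-number pairs had an r over 0.1 between their deviations (median 0.0031). In experiment 2 it was 5 of 12 libraries and 6 of 18 pairs (median 0.045, from -0.51 to 0.54). The 0.62 given below for 1 such pair exceeds this range, for a reason not traced.

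Leaving out each library in turn, which also removes a replicate, gave ranges of 188 to 824 for bryostatin alone, 66 to 96 for IL-4, 172 to 371 for bryostatin with IL-4, 588 to 689 with LPS and 242 to 434 with LPS and IFN-gamma. The difference with IL-4 stayed at 0 and that with LPS and IFN-gamma gave 4 to 19. LPS gave 5100 to 7032, LPS and IFN-gamma 8454 to 9997, and LPS and IFN-gamma against LPS 4631 to 5239. The untreated groups gave 0 to 784, with 784 without untreated experiment 1 replicate 1 and 691 without untreated experiment 2 replicate 1. Genes higher in all 4 ran from 14 to 26 and lower from 9 to 29. Raised and then lower genes ran from 0 to 6 for IL-4, 172 to 296 for LPS and 39 to 111 for LPS and IFN-gamma. For IL-4 the 0 came without IL-4 with bryostatin replicate 1 and the 6 without IL-4 replicate 1.

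Splits of 3 against 3 libraries number 10, too few for a share under 0.05. The real count and the highest of the other splits were 91 and 0 for IL-4, 644 and 0 for bryostatin with IL-4, 6164 and 0 for LPS, 1108 and 0 for bryostatin with LPS, 9339 and 1 for LPS and IFN-gamma, 543 and 43 for bryostatin with LPS and IFN-gamma, and 5791 and 0 for LPS and IFN-gamma against LPS, each with 1 split as large. For bryostatin alone 2 splits were as large, and the other, bryostatin replicates 1 and 3 with untreated experiment 2 replicate 3, called 3595 against 565, which points to a structure of the samples. For the untreated groups all 10 splits were as large as 0, with 4606 in the split that exchanges the libraries labelled replicate 1. Depth limits the genes near 0.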

Other observations

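Tests of Y-linked transcripts, gene length and long non-coding RNA were written down before their results were seen, and all other tests here were chosen after.

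Oligodendrocyte precursor genes moved apart with bryostatin in LPS-treated glia. Without the untreated libraries labelled replicate 1, Sox10 fell with a log2 change of -1.85 ± 0.12 (edgeR adjusted p = 1.19e-08) with bryostatin and LPS. Gpr17, a receptor of precursors about to mature, fell with a log2 change of -1.57, Lhfpl3 with -1.45, Cacng4 with -1.04, Bmp4 with -0.76 and Matn4 with -0.64, while the proteoglycan Cspg4 rose by 0.89 and Sox8 by 0.33. Of 23 precursor genes measured, 2 rose and 6 fell. With LPS and IFN-gamma, 2 rose (Pdgfra 0.86, Cspg4 1.04) and 6 fell, among them Sox10 with -1.14 and Gpr17 with -2.14. With both libraries kept, only Cspg4 (0.89) and Bmp4 (adjusted p = 0.0478) were called with LPS, Bmp4 in none of the 6 fits that each left out 1 library (highest 0.191, without LPS with bryostatin replicate 1), and only Cspg4 (1.04) and C1ql1 (-0.89) with LPS and IFN-gamma. Sox10 then had adjusted p values of 0.178 and 0.549 and Gpr17 of 0.245 and 0.342, at folds within 0.01 of those above. These genes other than Pdgfra, Cspg4, Bmp4 and C1ql1 were chosen after their values were seen. A lower share of precursors cannot by itself raise Cspg4, Sox8 or Pdgfra. Their cell source was not tested, so a lower share stays open for the genes that fell. A higher share of fibroblasts or pericytes, which also express Cspg4, would raise their own genes, but the medians of their lists were -0.15 (quartiles -0.46 to -0.05) and -0.16 (-0.36 to -0.04), and no member exceeded 0.41, below the 0.89 of Cspg4. With LPS and IFN-gamma the medians were -0.03 (-0.23 to 0.16) and -0.17 (-0.29 to 0.01), 2 fibroblast genes and 1 pericyte gene rose, and no member exceeded 0.62, below the 0.86 of Pdgfra. Neither list shares a gene with another, and Col1a2, the most abundant fibroblast gene, stood at 2210 ± 214 CPM with LPS and 1760 ± 404 CPM with bryostatin, and Acta2, the most abundant pericyte gene, at 221 ± 20.8 and 202 ± 30.4 CPM. A change of state within precursors, alone or with a change of share, stays open and was not tested.

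The libraries labelled replicate 1 of both untreated groups resemble the other experiment. Each correlates better with the other experiment's untreated libraries than with its own group, by at least 0.033 in mean Pearson r, and the precursor genes lie out of place in both, which is what exchanged labels would give. Y-linked transcripts (Ddx3y, Eif2s3y, Kdm5d and Uty summed) stood at 104 and 60.6 CPM in these 2 libraries, and the remaining libraries of the experiments overlap (76.4 to 101 and 65.3 to 112 CPM), so they decide nothing on exchanged labels. RNA of other cells added to 1 library is argued against, since 8 of 22 precursor genes are over 4-fold lower in the library labelled untreated experiment 1 replicate 1, which added RNA cannot do. Exchanged labels thus remain a likely explanation that these values do not prove, and no biological explanation was tested.

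Replicate 2 of bryostatin and of IL-4 with bryostatin stand apart from their groups, and their deviations correlate across 14250 genes (Pearson r 0.62, where genes are not independent replicates). Deviations ran against gene length, with a Spearman rho of -0.6 in bryostatin replicate 2 and -0.47 in IL-4 with bryostatin replicate 2, so a gene length bias could be the cause. The trend is not particular to them, with -0.5 in LPS and IFN-gamma replicate 1, -0.48 in LPS and IFN-gamma with bryostatin replicate 3, -0.43 in untreated experiment 2 replicate 1 and -0.39 in LPS with bryostatin replicate 1. A loss of long non-coding transcripts as a class is argued against, as their median deviation less that of protein-coding genes was -0.05 and 0. Single nuclear RNAs, chosen after their values were seen, were low in bryostatin replicate 2, with Malat1 at 92.6 CPM against 440 and 653 CPM in replicates 1 and 3, Kcnq1ot1 at 0.367 against 3.13 and 6.1 CPM and Xist at 16.7 against 72.3 and 75.1 CPM, and so was the coding gene Hipk2, at 8.69 against 86.2 and 93.1 CPM. Malat1 and Hipk2 were also low in untreated experiment 2 replicate 1, at 74.9 and 4.19 CPM. Lower RNA quality in these libraries thus stays open and was not tested. Sequencing depth is also argued against, since the totals of both replicate 2 libraries, 18.7 and 18 (in units of 1e6 counts), lie within the 17.3 to 28.7 of the other libraries of the experiment. Fold changes ran with length across genes too, with a rho of 0.18 for bryostatin alone, 0.41 for IL-4 and -0.12 for bryostatin with IL-4, so part of the small changes in experiment 2 may carry this trend. No biological explanation was tested.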
